A study of Mus musculus with 4 samples.

How the data were processed

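The arrays were NimbleGen mouse 3x720K whole-genome tiling arrays, 1 for each of 3 androgenetic haploid embryonic stem cell lines and 1 for kidney DNA hybridised to itself. Per the labels, sample DNA was labelled with Cy3 and the male kidney reference with Cy5, all samples were of C57BL/6J background, and the stem cells were grown on feeder cells in 2i medium and collected without them. Per the file headers, the deposited probe tables come from the segMNT step of NimbleScan, whose version is not given in the sources used here. They hold log2 channel intensities and log2 ratios of sample over reference as scanned, after the authors' spatial correction, and after the authors' normalisation between channels, whose method is not given in the sources used here. The deposited tables also give the GC content of each probe as a fraction from 0 to 1. The series value table was checked to equal the normalised log2 ratio of the authors, and the authors' segment means were checked to be means of that ratio. Chromosome lengths matched NCBI37/mm9. The gene annotation at hand was of another build, so gene lists, the transgene source loci and the naming of genes were not run, and regions are given by position.

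The values used were the spatially corrected log2 ratios minus each array's median over 664420 autosomal probes, with no loess or quantile step, because these would assume like ratios across the genome. The median distance between neighbouring probes was 3537 bp, and at most 25 probes of a channel were saturated. Chromosome values were medians over probes. Window values were means over windows of 100 kb with at least 10 probes. The 3 lines were compared with the kidney array by limma (lmFit and eBayes, limma 3.58.1 in R 4.3.3), two-sided, over 21 chromosomes and separately over all windows, with Benjamini-Hochberg adjustment at 0.05. These fits have 2 residual degrees of freedom from the lines, and the lone kidney array is assumed to vary like the lines. The labels do not say whether the lines are independent in origin, so the p-values measure the spread between these lines. The Oct4-EGFP lines were compared with the Actin-EGFP line in a limma fit of 3 groups with 1 residual degree of freedom, in which no line can be left out. No paired analysis was possible because the lines and the kidney share only replicate number 1, and the kidney has 1 array. Segments were the authors', with their means centred on the autosomal median of the normalised ratio, and were counted on autosomes at a mean of at least 0.3 from 0 and at least 5 probes. Segments of the same direction counted as shared at a reciprocal overlap of at least 50%. For naming, called segments of the same direction that touched or overlapped, within a line or between lines, were merged into regions, so a merged region can be wider than any segment of a line and can join segments that do not meet the overlap for sharing. For each named region, the mean over probes of the values used here is given, so a region called on the authors' segment mean may have a mean under 0.3.

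Named windows were the 10 regions per direction with the largest absolute differences past the threshold, adjacent windows merged, and named segments the 10 merged regions per direction with the largest absolute segment means, among autosomes. The X and Y exceptions were described separately after their values were seen, as were the regions named only in a closing part. The comparisons, alternatives and this rule were fixed before the data were examined, except where a choice is said to follow the data.

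Alternatives were the series value table, the scanned ratio, normexp background correction with an offset of 50, other centrings, chromosome means, windows of 50 kb, 500 kb and 1 Mb, window medians, other probe minimums, lines against 0, a running median of 5 Mb removed, a GC correction, another variance model, other segment thresholds, probe minimums and overlaps, an own segmentation by recursive splitting, and each line left out in turn. The GC correction, the scanned ratio, the row for unplaced Y sequence, the own segmentation of other values, the robust fit and the running median in the Oct4-EGFP against Actin-EGFP comparison were chosen after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 did the rest.

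The steps were tested on simulated data. With 200 of 23980 windows changed, limma on 3 lines against 1 array recovered 0 at a log2 change of 0.1, 69 at 0.2, 198 at 0.3 and 200 at 0.5, with 0, 4, 3 and 9 unchanged windows called. The comparison of the Oct4-EGFP lines with the Actin-EGFP line recovered 2, 173, 200 and 200, with 1, 8, 10 and 8 unchanged windows called. In 100 simulated sets of 21 chromosomes the X was recovered in 69 and the Y in 98, and 7 autosomes were called over all sets. The own segmentation recovered 41, 112 and 93 of 200 blocks of 5, 10 and 30 probes at 0.3, and 199, 200 and 200 at 0.5, with 0 other segments. A block counted only if its segment mean reached 0.3, so noise alone put many blocks simulated at 0.3 under this bound. The counts at 0.3 therefore do not measure the segmentation alone. All simulated noise was independent between probes, windows and chromosomes and held no regional waves. The false calls in these simulations therefore do not carry over to the arrays. On the kidney array the own segmentation called 182 gains and 33 losses.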

Results

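Genomic DNA of 3 mouse androgenetic haploid embryonic stem cell lines was hybridised against genomic DNA of a male C57BL/6J kidney on whole-genome tiling arrays. Androgenetic haploid embryonic stem cells are grown from embryos that carry sperm-derived chromosomes only. Array comparative genomic hybridisation reads copy number along each chromosome as the log2 ratio of sample over reference fluorescence. AGH-EG-1 carried an Actin-EGFP transgene, and AGH-OG-2 and AGH-OG-3 carried an Oct4-EGFP transgene. A further array, with kidney DNA in both channels, was the control measured the same way. There was 1 array per line and 1 control array, and this number limits the precision of every comparison. Each array gave 713358 probe ratios, of which 664420 were autosomal, 42531 on the X chromosome, 688 on the Y chromosome and 5719 in unplaced Y sequence. The noise between neighbouring probes had an SD of 0.137 on the kidney array, 0.145 for AGH-EG-1, 0.124 for AGH-OG-2 and 0.124 for AGH-OG-3. All positions are on the mouse build NCBI37/mm9, and the values below are log2 ratios set to an autosomal median of 0 on each array.

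The first comparison asked which whole chromosomes differed in copy number between the haploid lines and the same-background male kidney. The X chromosome was higher than in kidney in 3 of 3 lines, by 0.62 ± 0.070 (SE, n = 3 lines against 1 array; limma adjusted p = 0.0288). Its median was 0.75 in AGH-EG-1, 0.74 in AGH-OG-2 and 0.62 in AGH-OG-3, against 0.08 on the kidney array. The Y chromosome was lower in 3 of 3 lines, by a difference of -1.70 ± 0.094 (SE, limma adjusted p = 0.00657), with medians of -1.55, -1.67 and -1.75 against 0.045 in kidney. A male diploid genome carries its X and its Y at a lower dose than each autosome pair, whereas a haploid genome with an X chromosome, or its diploid descendants, carries the X at the dose of the autosomes and lacks a Y. The lines did not differ from kidney by more than 0.073 at any autosome. Among the 19 autosomes, chromosomes 7 and 17 passed the test as higher, by 0.034 and 0.030, and chromosomes 1, 3, 14 and 16 as lower, by differences of -0.025, -0.045, -0.029 and -0.039, each in 3 of 3 lines and each at a limma adjusted p of 0.0337. Chromosome 11 had the highest autosomal median in every line, 0.053, 0.060 and 0.088, and did not pass (difference 0.073, adjusted p = 0.0551). Leaving out AGH-EG-1 or AGH-OG-2 ended the X call and every autosomal call, and leaving out AGH-OG-2 ended the Y call. With any line left out the X difference stayed at 0.60 to 0.66 and the Y difference at -1.76 to -1.65, with 1 residual degree of freedom. How many autosomes passed also depended on the centring and the chromosome summary used. An exact permutation test of 3 lines against 1 array cannot go below a p of 0.25. The lines shared a slide and the kidney array lay on another, so slide and group cannot be told apart in this comparison. The X and Y medians of each line, however, are ratios to male kidney DNA on its own array, where no autosome median exceeded 0.088. The X and Y changes thus do not rest on the comparison between slides, but this does not settle the small autosomal differences. After normexp background correction the Y difference was -0.78.

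**Figure D1:**
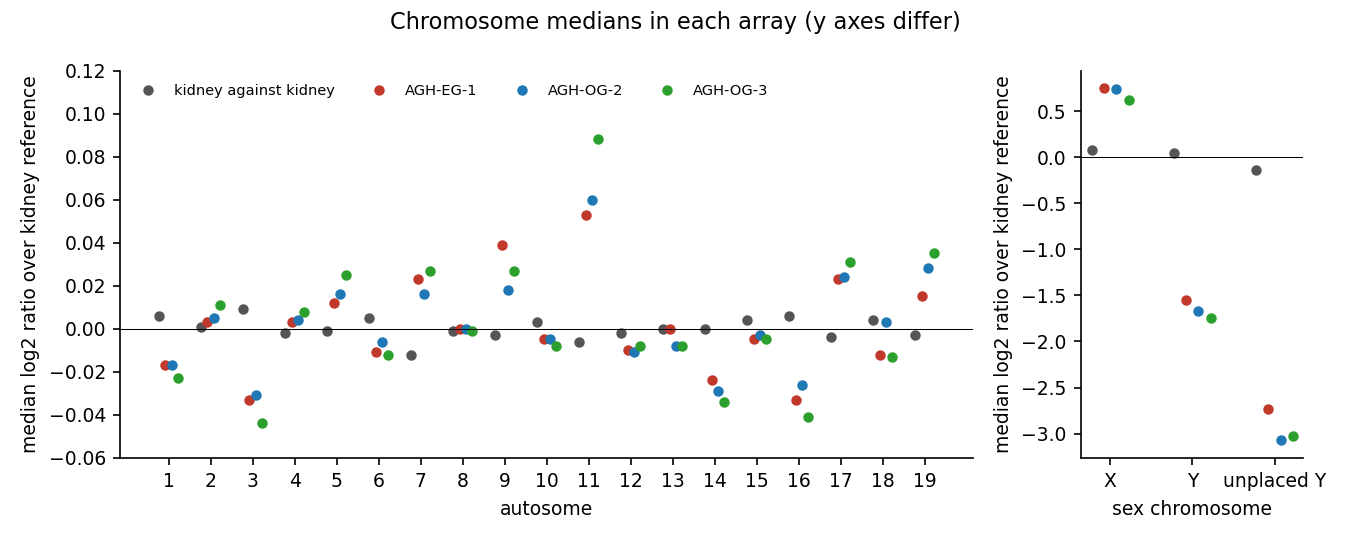
Median log2 ratio over the kidney reference of each autosome (left) and of X, Y and unplaced Y sequence (right, another y axis), with 1 point per array. The X medians of the 3 lines lie between 0.62 and 0.75 and the Y medians between -1.75 and -1.55, while no autosome of a line exceeds 0.088.

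Along the X chromosome the gain was nearly complete: 1556 of 1567 windows of 100 kb were higher in the lines than in kidney, 99.3% of them, with a median difference of 0.59 and 5 to 95% limits of 0.40 to 0.84. The exceptions lay in 2 places. Between positions 120303265 and 122697303 of the X chromosome, 430 probes averaged 0.08 in AGH-EG-1, -0.06 in AGH-OG-2 and -0.11 in AGH-OG-3 against -0.01 in kidney, and 5 windows there were lower than in kidney. Near the distal end, at X 166402816 to 166498497, 15 probes averaged -0.63 in AGH-EG-1, 0.39 in AGH-OG-2 and 0.09 in AGH-OG-3 against -0.19 in kidney. On the Y chromosome all 28 windows were lower in the lines. The X ratio was lower in AGH-OG-3 than in AGH-OG-2 and in AGH-EG-1 in all 160 windows of 1 Mb, a difference between single arrays that was not tested. With a running median of 5 Mb removed from each array, 14.7% of X windows were higher and 35.7% of Y windows lower, since that step removes any change as wide as a chromosome.

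**Figure D2:**
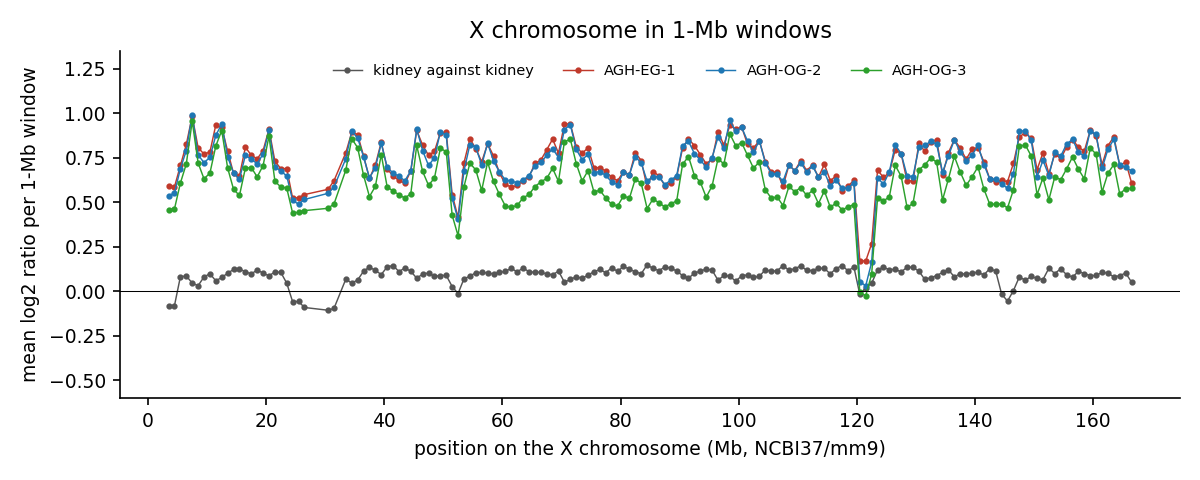
Mean log2 ratio of 1-Mb windows along the X chromosome (position in Mb) in each array. The lines run above the kidney array, nearest to it around 120303265 to 122697303, where AGH-OG-3 falls below kidney in 1 window, and AGH-OG-3 runs below the other lines in 160 of 160 windows.

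The second comparison asked which stretches of the autosomes differed between the lines and kidney. Its SEs and p-values rest on the spread between 3 lines on the same slide, which limma drew towards a variance pooled over all windows. The pooled part had 11.8 prior degrees of freedom against 2 residual ones, so the small p-values rest mainly on it. These SEs and p-values take in no spread of the kidney array or between slides. Of 23980 autosomal windows of 100 kb, 5385 were higher in the lines (22.5%) and 5914 lower (24.7%), mostly by little: the difference reached 0.3 in 199 of the higher and 42 of the lower windows. The highest window lay on chromosome 9 within 39900001 to 40800000, with a difference of 0.65 ± 0.044 (SE, limma adjusted p = 3.6e-08) and values of 0.64, 0.71 and 0.73 in the lines against 0.04 in kidney. Higher windows with a difference above 0.5 also lay on chromosome 4 within 131600001 to 136000000 (0.57 ± 0.043), on chromosome 8 within 72000001 to 75300000 (0.53 ± 0.043) and on chromosome 17 within 27600001 to 30200000 (0.52 ± 0.043). On chromosome 14 within 26300001 to 27200000 the difference was 0.60 ± 0.15, from 0.63 and 0.75 in the Oct4-EGFP lines and 0.14 in AGH-EG-1. The other 5 named higher regions, on chromosomes 2, 4, 7 and 8, differed by 0.39 to 0.42. The lowest window lay on chromosome 3 within 25200001 to 26500000, with a difference of -0.72 ± 0.041 (limma adjusted p = 5.3e-09) and values of -0.70, -0.75 and -0.74 in the lines against -0.01 in kidney. The other 9 named lower regions, on chromosomes 1, 2, 8, 10, 11, 12, 14 and 16, were regions of 1.5 to 5.2 Mb with top differences of -0.39 to -0.32, and in each the kidney array itself lay above 0. Across 1-Mb autosomal windows, which are not independent replicates, the lines correlated with each other at 0.87, 0.87 and 0.99 and with the kidney array at -0.49, -0.48 and -0.54. The counts fell to 10.6% higher and 9.3% lower after a running median of 5 Mb was removed and to 14.2% and 14.99% after a correction for the probes' GC content, the last chosen after seeing the data.

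The design asks for the copy number variation of each line, which was read from the authors' segments with a mean at least 0.3 from 0 and at least 5 probes. AGH-EG-1 had 56 gained and 32 lost autosomal segments, AGH-OG-2 52 and 3, and AGH-OG-3 55 and 6, whereas the kidney array had 0 of either. Most were short, with medians of 43.3, 52.1 and 56.6 kb for gains and 57.5, 15.4 and 35.0 kb for losses. The median segment mean of gains was 0.44, 0.36 and 0.38, below the X medians of 0.75, 0.74 and 0.62 on the same arrays. Most gains thus fell short of the X change, and a call does not by itself show a whole extra copy. Lost segments covered 3.59 Mb in AGH-EG-1, 0.063 Mb in AGH-OG-2 and 0.485 Mb in AGH-OG-3. Adjoining segments can be pieces of the same stretch, so the segment counts are not counts of separate losses. After merging, the loss regions called in a line alone numbered 20 in AGH-EG-1, 2 in AGH-OG-2 and 5 in AGH-OG-3. Of the 20 in AGH-EG-1, 10 lay more than 3 SE over probes below both other lines. AGH-EG-1 had lost segments on chromosome 14 at 53302096 to 54388877, where 299 probes averaged -2.33 ± 0.061 (SE over probes), against -0.06 in AGH-OG-2, -0.05 in AGH-OG-3 and -0.03 in kidney. AGH-EG-1 also had lost segments on chromosome 13 between 65453684 and 66469133, where 4 named regions averaged -0.78 to -0.59. Others lay on chromosome 14 at 69873924 to 70087606 (-0.83 ± 0.022) and on chromosome 3 at 92017684 to 92086855 (-0.72 ± 0.024). This chromosome 3 stretch read -0.24 and -0.20 in the Oct4-EGFP lines and -0.18 in kidney, so the control shared their offset. With the series values it read -0.55 in AGH-EG-1, -0.02 in AGH-OG-2, -0.04 in AGH-OG-3 and -0.01 in kidney. On chromosome 17 at 35635775 to 35651931, 5 probes averaged -2.30 ± 0.194 in AGH-EG-1, 0.26 in AGH-OG-2 and 0.39 in AGH-OG-3 against -0.20 in kidney. The sample signal of this block in AGH-EG-1 was still brighter than 73.1% of runs of 5 neighbouring autosomal probes. Its low ratio therefore does not by itself show a loss. In AGH-EG-1 this block lay between gained segments that ended at 35634006 and began at 35654373, and in AGH-OG-2 a gained segment of 6 probes, 35635775 to 35654373, covered the block itself (segment mean 0.55). AGH-OG-3 alone had a lost segment on chromosome 5 at 14903113 to 15219512, where 76 probes averaged -1.0 ± 0.041 against 0.22 in AGH-EG-1, 0.24 in AGH-OG-2 and -0.17 in kidney. This stretch was called as a gain in AGH-OG-2 (segment mean 0.39) and, up to 15204984, in AGH-EG-1 (segment mean 0.31). All 3 lines thus had a call there, in opposite directions. Gains called in AGH-EG-1 alone lay on chromosome 5 at 135176158 to 135207124 (1.08 ± 0.032), on chromosome 17 at 27425164 to 27583650 (0.90 ± 0.025) and on chromosome 14 at 23365023 to 23386134 (0.78 ± 0.066) and 23722283 to 23749447 (0.76 ± 0.034). There is 1 array per line, so no test compares lines here, and a call in a line alone, as for 20 loss and 27 gain regions in AGH-EG-1, does not show a difference between lines. An own segmentation of the authors' ratios, chosen after seeing the data, called 301 gains and 62 losses on the kidney array itself, against 239 and 94 in AGH-EG-1, 289 and 35 in AGH-OG-2 and 305 and 33 in AGH-OG-3, and normexp background correction gave 1.65 for the chromosome 5 gain, 1.41 for the chromosome 17 gain, 1.31 and 1.33 for the chromosome 14 gains, -1.34 for the loss at 69873924 and -1.23 for that at 65657073 in AGH-EG-1.

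**Figure D3:**
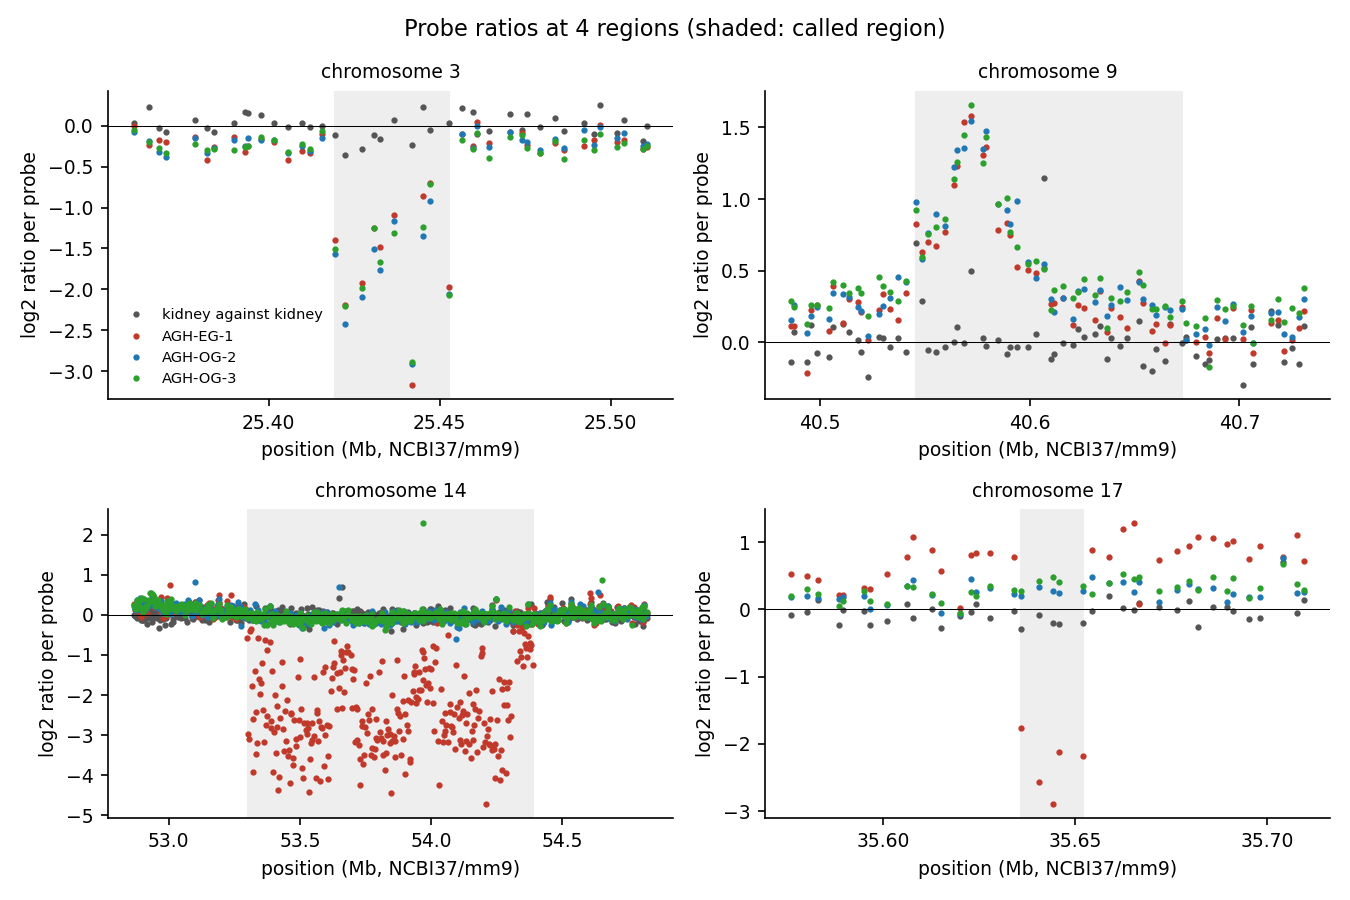
Log2 ratio of each probe against position (Mb) in 4 regions, on chromosomes 3, 9, 14 and 17, with 1 colour per array and the called region shaded. The chromosome 3 loss and the chromosome 9 gain are seen in all 3 lines, and the chromosome 14 loss in AGH-EG-1 only. The chromosome 17 block has a low ratio in AGH-EG-1 only. Its sample signal there was still brighter than 73.1% of runs of 5 neighbouring autosomal probes, so whether this is a loss stays open.

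Segments found in more than 1 line are of interest because all lines were compared with the same reference DNA. With reciprocal overlap of at least 50%, 12 gains and 1 loss were shared by 3 lines, and 20 gains and 0 losses by 2 lines. The kidney array had none of them, but with kidney DNA in both channels it cannot show a variant of the reference. Its lack of segments therefore does not tell whether a shared segment comes from the lines or from the reference animal. The loss shared by 3 lines was on chromosome 3 at 25419265 to 25452686, where 10 probes averaged -1.60, -1.78 and -1.68 (mean -1.69, SD 0.087, n = 3) against -0.10 in kidney. The merged region on chromosome 8 at 72701368 to 72793352 (mean of the lines 0.54, SD 0.039) held a gain shared by 3 lines. Other merged regions held gained segments of all 3 lines whose bounds differed too much for that overlap. On chromosome 9 at 40545617 to 40672624 (mean 0.60, SD 0.049) no segment was shared by more than 2 lines. On chromosome 4 the gains of AGH-EG-1 and AGH-OG-2 covered 60.3 and 52.1 kb at the distal end of 131798237 to 133384942, and the larger gain of AGH-OG-3 covered 1569 kb (region mean 0.29, SD 0.058). On chromosome 4 at 35802658 to 35838338 the segments of AGH-EG-1 and AGH-OG-2 also overlapped by less than 50%, and the mean was 0.65, 0.65 and 0.55 in the 3 lines. On chromosome 14 at 26696171 to 27109046 the gain was called in the Oct4-EGFP lines, at 0.62 and 0.72, and AGH-EG-1 lay at 0.14; normexp gave 1.12 in AGH-OG-3. At a segment threshold of 0.5, 2 gains and 1 loss were shared by 3 lines.

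The last comparison set the Oct4-EGFP lines against the Actin-EGFP line, the labels' only division among the lines; AGH-EG-1 is the only Actin-EGFP line, so transgene and line cannot be told apart. Of 23980 autosomal windows, 51 were higher (0.213%) and 63 lower (0.263%) in the Oct4-EGFP lines. The top window on chromosome 14 within 53300001 to 54400000 was higher by 2.81 ± 0.048 (SE), from -2.90 in AGH-EG-1 and -0.09 in both Oct4-EGFP lines. Windows on chromosome 13 within 65400001 to 66800000 (0.94), chromosome 14 within 69800001 to 70100000 (0.87), chromosome 4 within 41700001 to 42900000 (0.59) and chromosome 14 within 26700001 to 27100000 (0.55) were also higher. Lower windows lay on chromosome 13 within 32800001 to 33100000 (-0.78), chromosome 14 within 42000001 to 44400000 (-0.72) and chromosome 17 within 27400001 to 27600000 (-0.69). The remaining named regions differed by 0.18 to 0.39 if higher, on chromosomes 3, 8, 13, 14 and 17, and by -0.40 to -0.22 if lower, on chromosomes 9, 14 and 17. On chromosome 5 within 14900001 to 15200000 the difference of -0.63 joined 0.27 in AGH-OG-2 with -0.98 in AGH-OG-3, against 0.27 in AGH-EG-1, and with the robust variance fit, chosen after seeing the data, it did not pass (adjusted p = 1.0). Only the pair of Oct4-EGFP lines informs the spread, 1 residual degree of freedom, and limma pooled it into an SE of 0.048 for every window, so the p-values of single windows are not given. With the series values 69 windows were higher and 101 lower, and with a running median removed, chosen after seeing the data, 44 were higher and 24 lower, which turns the balance.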

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

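The tests of slides in the first pattern, of male DNA and of compressed ratios in the second, and both tests of the third were chosen only after the result was seen; those of GC content and of regional waves were set before it.

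In all 3 lines the autosomal ratio rose and fell over megabases in the same places, with an SD over 1-Mb windows of 0.106, 0.092 and 0.125 against 0.026 in kidney. The mean correlation between lines over these windows was 0.908 and stayed at 0.815 after a quadratic GC trend was removed from each array (lowest pair 0.726), above the bound of 0.6 set for a pattern that a GC trend does not account for alone, although the correlation of the kidney array with the lines went from -0.54 to -0.48 before to 0.03 to 0.10 after. No slide held both the kidney array and a line (0 of 2 slides), so a difference between slides and hybridisations cannot be told apart from one between cell lines and kidney. The pattern may therefore come from the hybridisation or from the cells, and a biological difference between growing cells and kidney tissue stays open as untested.

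The X chromosome ratio was lower in AGH-OG-3 (0.62) than in AGH-OG-2 (0.74) and AGH-EG-1 (0.75). Admixed male diploid DNA would need an unplaced Y ratio of 0.214 on the linear scale, whereas AGH-OG-3 had 0.123, beside 0.150 in AGH-EG-1 and 0.119 in AGH-OG-2. Compressed ratios would lower every change on this array. Over 17 merged regions called in all lines the median ratio of AGH-OG-3 to the others was 1.09, and 0.765 of the regions were at 1 or more, against 0.825 for the X. These regions were kept only where AGH-OG-3 was itself called. Its autosomal 1-Mb windows also had a slope of 1.34 on those of AGH-OG-2, and such waves can raise gains. This ratio therefore cannot set compression aside. Y sequence was not chosen by calls. Its Y median was -1.75 in AGH-OG-3, against -1.55 in AGH-EG-1 and -1.67 in AGH-OG-2. For unplaced Y the medians were -3.02, against -2.74 and -3.07. These values argue against a compression of losses on this array as strong as that of the X. A compression of gains alone stays open. For stronger regional waves, autosomal windows matched on GC differed between AGH-OG-3 and AGH-OG-2 by 0.264 of the X difference, under the bound of 0.5. The interval was 0.246 to 0.282, from 1-Mb windows resampled as if independent, and the value was 0.26 without a GC bin of 6 windows. Matching on GC reaches only the part of the waves that follows GC, so this does not exclude stronger waves. Of all autosomal 1-Mb windows, 0.083% lay at or below the X median difference of -0.109. Loss of the X from some AGH-OG-3 cells is a further hypothesis, which was not tested on these arrays. A difference between hybridisations could also give the lower X ratio.

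On chromosome 17 at 35635775 to 35651931, 5 probes lay at -2.30 in AGH-EG-1 and at 0.26 and 0.39 in the Oct4-EGFP lines. For a loss of this block from AGH-EG-1, the sample signal fell by 1.79 from kidney to AGH-EG-1, where equally bright unplaced Y probes had a median of -3.30; 8.63% of these 649 probes fell as little, between the bounds of 5% and 75%, so this stays open. For extra copies of the block in the kidney reference and the Oct4-EGFP lines, 37 of 664344 runs of 5 neighbouring autosomal probes were as bright in the kidney sample channel, whereas in AGH-EG-1 the block was brighter than 73.1% of runs; such runs are different probes, but X runs were dimmer than autosomal ones by 0.82 in male kidney and by 0.15 in AGH-EG-1, with an SD over autosomal runs of 0.35 in kidney. In the reference channel of the AGH-EG-1 array only 3 runs were as bright as the block. The low ratio there thus joined a rarely bright reference with a sample signal that was not dim among runs. Extra copies may be a candidate explanation beside a loss. Pou5f1, whose regulatory DNA drives Oct4-EGFP reporters, lies on chromosome 17, but whether the block holds it was not checked. Brightness does not count copies, and the labels call the kidney wild type. Free construct DNA in the reference would look alike and was not tested. This pattern took the place of another, the regions called in AGH-EG-1 alone, for which earlier tests of a noisier array and of sequence variants were run and decided nothing firm: isolated low probes were 1.56 times as dense around its loss regions as elsewhere (interval 0.663 to 3.13, from 8 probes), while in the chromosome 14 loss at 53302096 to 54388877 0.826 of 299 probes lay below the midpoint between it and the other lines, so this loss is not a few scattered low probes.

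The other results stood out because the Oct4-EGFP lines differed from the Actin-EGFP line by the limma test of that difference, which rests on 1 array in the Actin-EGFP arm and 1 pooled SE from the Oct4-EGFP pair, so it does not measure the spread between Actin-EGFP lines. The windows that passed on autosomes were 51 higher and 63 lower in the Oct4-EGFP lines, in 11 and 19 regions once adjacent windows were merged. At an unadjusted limma p under 0.05 there were 572 and 261 of 23980. That is no more than this threshold would give without any difference, so these counts do not show wider differences. On chromosome 14 within 53300001 to 54400000 the top window differed by 2.81, and within 69800001 to 70100000 by 0.87. On chromosome 13 the top windows within 65400001 to 66800000 and 32800001 to 33100000 differed by 0.94 and -0.78. The top window on chromosome 4 within 41700001 to 42900000 differed by 0.59. Further top windows on chromosome 14, within 26700001 to 27100000 and 42000001 to 44400000, differed by 0.55 and -0.72. The top window on chromosome 17 within 27400001 to 27600000 differed by -0.69. On chromosome 5 within 14900001 to 15200000 the difference was -0.63, from 0.27 in AGH-OG-2 and -0.98 in AGH-OG-3, which lie on opposite sides of 0. Unplaced Y sequence, which the chromosome comparison does not use, stood out as a signal beyond that of the control array, with a difference of -2.81 ± 0.174 (SE, limma adjusted p = 0.00728 with 22 chromosomes) from medians of -2.74, -3.07 and -3.02 in the lines and -0.14 in kidney.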

How the results depend on the processing

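The GC correction, the own segmentation of the series values, of the scanned ratio and after normexp, and the running median for the Oct4-EGFP against Actin-EGFP windows were chosen after seeing the data. Of 255 alternative values for the main results, 165 stayed within their limits, 3 kept their direction without passing the threshold and 87 moved. Of 60 for the named segment regions, 48 stayed, 12 moved and none turned its direction. A count or percentage stayed if it lay within a fixed fold of its main value. Chromosome differences stayed if they kept their direction and their side of the threshold. Regions stayed if they moved by less than the SD over their probes, which is a wide band. The tally includes settings that could change no count, such as a minimum of 2 probes. Unless a cause is given, the cause was not tested. The X difference was 0.60 to 0.66 and the Y difference -1.76 to -1.65 when a line was left out, and fewer lines leave 1 residual degree of freedom: without AGH-EG-1 the X difference was 0.60 (adjusted p = 0.125), and without AGH-OG-2 it was 0.60 (0.109) and that of Y -1.69 (0.109). Over all alternatives the adjusted p ran from 0.0024 to 0.125 for X and from 0.00085 to 0.109 for Y. The autosomes past the threshold numbered 13 for lines against 0, 11 when centred on all probes, 1 with chromosome means and 0 to 4 with a line left out. Autosomal windows were higher in 0.83% and lower in 0.175% when a difference of at least 0.3 was required, a stricter rule by construction. They were higher in 36.3% for lines against 0, higher in 10.6% and lower in 9.3% with the running median removed, and 14.2% and 14.99% with the GC correction. Leaving out a line gave 15.2 to 24.0% higher and 18.2 to 24.9% lower, 99.2 to 99.3% of X windows and 100% of Y windows. With the running median removed, 14.7% of X windows were higher and 35.7% of Y windows lower, because it takes out changes wider than 5 Mb. Windows lower in the Oct4-EGFP than the Actin-EGFP lines were 0.421% with the series values and 0.10% with the running median removed.

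Gains are given in the order AGH-EG-1, AGH-OG-2, AGH-OG-3, then losses in the same order. A threshold of 0.2 gave 104, 132 and 132, then 75, 14 and 20, and a threshold of 0.5 gave 20, 12 and 12, then 19, 1 and 2. With at least 10 probes there were 37 gains in AGH-EG-1 and 1 loss in AGH-OG-2. AGH-OG-3 had 12 losses with no centring and 11 when centred on all probes. The own segmentation gave 214, 251 and 290, then 92, 31 and 36, and called 182 gains and 33 losses on the kidney array. With the kidney array subtracted it gave 162, 199 and 256, then 152, 117 and 105. Of the series values it gave 239, 289 and 305, then 94, 35 and 33, and 301 gains and 62 losses on the kidney array. Of the scanned ratio it gave 198, 264 and 267, then 91, 31 and 33, and 179 and 32 on the kidney array. After normexp it gave 388, 531 and 865, then 204, 87 and 110, and 265 and 51 on the kidney array. With the series values the control thus gave gains within the range of the lines and more losses than either Oct4-EGFP line. In the other settings its gains were fewer than those of each line. Its losses still exceeded those of AGH-OG-2 in the own segmentation (33 against 31) and in that of the scanned ratio (32 against 31). After normexp they did not (51 against 87). Gains shared by 2 lines were 46 at a threshold of 0.2, 9 at 0.5, 34 with the kidney array subtracted, 143 with the own segmentation after normexp and 17 to 19 with a line left out. Losses shared by 2 lines were 2 at a threshold of 0.2, 3 with the own segmentation, 31 with the kidney array subtracted, 3 of the series values, 5 of the scanned ratio, 29 after normexp and 1 with any line left out, where a loss of 3 lines becomes one of 2 by construction. Gains shared by 3 lines were 2 at a threshold of 0.5, 25 with the own segmentation, 34 with the kidney array subtracted, 35 of the series values, 24 of the scanned ratio, 106 after normexp and 6 at an overlap of 80%. Losses shared by 3 lines were 2 with the own segmentation, 45 with the kidney array subtracted, 2 of the series values, 2 of the scanned ratio and 22 after normexp.

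Probes outside segments with an absolute mean over 1 gave no Y value, since all 688 Y probes lie in such segments. A minimum of 2 probes changed no segment count, since the authors' segments hold at least 5. The alternatives for gene lists were not run. Normexp brought the Y difference from -1.70 to -0.78 and the chromosome 14 loss at 53302096 in AGH-EG-1 from -2.33 to -2.39. The named regions that moved did so under normexp, away from 0, except 1 value with the series table, -0.55 for chromosome 3 at 92017684, which normexp put at -1.01. In AGH-EG-1 normexp gave -3.29 for chromosome 17 at 35635775, 1.41 for chromosome 17 at 27425164, 1.65 for chromosome 5 at 135176158, 1.31 and 1.33 for chromosome 14 at 23365023 and 23722283, -1.34 for chromosome 14 at 69873924 and -1.23 for chromosome 13 at 65657073. It gave -2.57 for chromosome 3 at 25419265 in AGH-OG-2, and -1.43 for chromosome 5 at 14903113 and 1.12 for chromosome 14 at 26696171 in AGH-OG-3. What signal over background limits was not tested. No paired analysis was possible because the groups share only replicate number 1.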

Other observations

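Gains called in all lines had unequal heights along their length, given here for regions around the lines' own highest running mean of 3 probes. That centre was chosen from the same values, so a fall away from it is built in and is not a test. On chromosome 9 at 40545617 to 40672624 the mean was 1.52 within 5 kb (SD 0.061, n = 3 lines), 1.15 at 5 to 15 kb, 0.75 at 15 to 30 kb and 0.32 at 30 to 50 kb, and 0.25, 0.02, 0.08 and 0.06 in kidney. On chromosome 17, around position 87808902, it was 0.89, 0.62, 0.46 and 0.26 at these steps. On chromosome 13, around position 104311339, it was 0.77, 0.62, 0.30 and 0.12. On chromosome 6 at 47602381 to 47729084 it was 0.085, 0.22, 0.24 and 0.15.

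Several wide regions called in AGH-EG-1 alone lay on chromosomes 4, 13 and 14. On chromosome 14 at 42017152 to 44255171, 555 probes averaged 0.53 in AGH-EG-1 and -0.07 in both Oct4-EGFP lines against -0.14 in kidney. On chromosome 13 at 32803465 to 33060565, 72 probes averaged 0.70 in AGH-EG-1, -0.08 in AGH-OG-2 and -0.10 in AGH-OG-3. On chromosome 4 at 41732421 to 42728778, 198 probes averaged -0.46 in AGH-EG-1, 0.01 in AGH-OG-2 and 0.07 in AGH-OG-3 against -0.11 in kidney.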
